A study of Mus musculus with 4 samples.

How the data were processed

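Gene expression and hashtag antibody libraries of sorted lineage-negative, Sca-1-positive, Kit-positive mouse bone marrow cells were analysed for the 10x Genomics GEM-X and v3.1 chemistries. The submitters call the cells HSCs. The deposited matrices hold raw UMI counts per feature and cell barcode for 32285 genes and 4 hashtags, restricted to barcodes called as cells and not divided by tube. Per the file headers the counts were made with Cell Ranger 8.0.1 (GEM-X) and 7.1.0 (v3.1), while the deposited processing notes name 7.0.0 and the mm10 genome, so the version goes with the chemistry. No label ties a matrix to a chemistry outright. The assignment was inferred from the matrix names and the Cell Ranger versions, the older of which came before GEM-X. A deposited text pairs each hashtag with a mouse and a tdTomato gate, and that pairing was used. The labels describe the sort in 2 ways, as 1 positive and 1 negative tube for both mice and as 4 hashed samples in 1 library, and the hashtags were taken to separate the mice.

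Cells were kept with at least 1000 genes and at most 10% mitochondrial UMIs, which kept 20140 GEM-X and 16721 v3.1 barcodes and left out 371 and 1034. Each hashtag was called positive per chemistry at a posterior of 0.5 in a 2-component Gaussian mixture of log10 UMIs (scikit-learn 1.9.0), and cells with exactly 1 hashtag were used. Cells with no hashtag (60 and 13) and with more than 1 (2093 and 2364, taken as doublets between tubes) were left out. Doublets within a tube carry 1 hashtag and remain, and Scrublet, run in scanpy 1.11.5, called 4.01% and 6.27% of cells and served as an alternative. Scrublet found 26.9% and 30.9% of the hashtag doublets.

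Counts were scaled to 10000 per cell and log1p transformed. Then 2000 variable genes were chosen within chemistry without cell cycle, mitochondrial and ribosomal genes and scaled within chemistry, and 30 principal components and 30 neighbours were used for Leiden clustering at resolution 1 (leidenalg 0.10.2, 5 iterations). Clusters were named from marker lists fixed before the data were examined, when at least 3 markers and 66.7% of those detected were raised by at least 0.5 on the log2 scale, so that a name such as HSC-like means these markers and not function. A cluster that met this was still left unnamed when another class had more markers among its 10 leading genes (683 cells), when at least 3 of the 10 were cell cycle or histone genes (2327 and 724 cells) or immunoglobulin genes (1642 cells, with 9 of 10 detected HSC markers raised), or when its UMIs were few and no marker led it (no cluster). Of 17 clusters 10 were named, and 7 unnamed ones held 46.9% of the cells. The thresholds and exceptions of naming were set after the data were seen. For shares of cells, the clustering was repeated without the genes called between the gates.

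Counts were summed per tube over cells and chemistries for the gates, and per tube and chemistry (8 sums) for the chemistries. The tests were edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; TMM, filterByExpr, estimateDisp, glmQLFit, glmQLFTest) with the mouse or the tube as a block and Benjamini-Hochberg adjustment at 0.05. Trended dispersions were held at 1e-04 or above, a floor set after the data were seen. Standard errors are the log2 fold change divided by the square root of F. They rest on a spread pooled over genes, not on the spread between the 2 mice. Both tubes of a mouse come from the same animal. As a check of this pairing, the difference between mouse 1 and mouse 2 in the positive tubes was compared with that in the negative tubes across genes (Pearson r 0.838 and Spearman rho 0.806 over 9368 genes, which are not independent replicates). The 26 gene lists, 11 of cell types and 15 of programs, were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry (limma 3.58.1). They are HSC, megakaryocyte-platelet, erythroid, granulocyte-monocyte, lymphoid, mast-basophil, B cell, T and NK cell, neutrophil, macrophage-dendritic, endothelial-stromal, G1/S, G2/M, quiescence, interferon, immediate early, MHC class II, aged HSC, fetal and neonatal HSC, receptor, glycolysis, oxidative phosphorylation, mitochondrial, microtubule, ribosomal and histone genes.

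Named genes followed a rule fixed before the data were examined: Tppp3 first, then up to 10 risen and 10 fallen genes with the largest log2 fold change among those past the test, with a mean of at least 10 CPM and the same sign in both mice (for the chemistries, in all 4 tubes) and both chemistries, and up to 4 members of each list. Unnamed gene models were skipped, as were families of near-identical copies by patterns of their symbols (histones and haemoglobins among them), which were set after the data were seen and do not cover Tgtp2 and Tmsb15b2. Of the genes picked this way, 1 between the gates and 1 list member are not reported here. Coordinates come from GENCODE M21 (mm10), matched for 32158 genes (99.6%).

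Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Depth was compared with an exact two-sided permutation test of 4 paired differences, and genes per cell also after thinning cells to 5000 UMIs. Intervals of fold changes came from 2000 resamplings of cells. Alternatives were no block, DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, each chemistry alone, another hashtag rule (largest hashtag of at least 10 UMIs and 3 times the next), removal of Scrublet doublets, at least 2000 genes with at most 5% mitochondrial UMIs, other resolutions (0.5 and 2), leaving out each tube, and removal of clusters. Tests were also run on simulated data: with 200 changed genes, 75.8% of those changed by 0.5 and 91.0% of those changed by 1 on the log2 scale were called between the gates over all cells, with 11 false calls. These counts were drawn independently per gene from the dispersion trend of the fit itself. They held no gate effect that differs between mice and no few rich cells. The false calls therefore do not measure the error rate in the real data. On simulated lists the preset correlation called a shift of 0.5 that the estimated correlation missed (adjusted p = 0.943 and 0.224), with 2 and 0 other lists called. Genes of these lists were also drawn independently, so the simulation cannot judge which correlation is right for the real data. With an estimated correlation, camera's test has only the residual degrees of freedom of the fit. These were 1 between the gates, 3 between the chemistries and 2 for the gate by chemistry. A list that misses there is therefore not shown to be unshifted. Other analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.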

Results

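Single-cell gene expression was measured in bone marrow cells of 2 male mice that carried a tamoxifen-inducible Cre under the Tppp3 gene and a Cre-dependent tdTomato reporter. Tppp3 encodes a tubulin polymerization-promoting protein. Tamoxifen was given at postnatal days 0 and 3, so tdTomato marked cells in which the Cre had been active in the newborn, and their progeny, and cells were collected at 3 months of age. The sort took lineage-negative, Sca-1-positive, Kit-positive cells, a compartment that holds haematopoietic stem cells (HSCs) and multipotent progenitors. The cells fell into 4 tubes, a tdTomato-positive and a tdTomato-negative tube from each mouse. Each tube carried its own hashtag antibody and was divided between the 10x Genomics GEM-X and v3.1 droplet chemistries. The series has 4 samples in 4 groups of 1: a gene expression library and a hashtag library per chemistry.

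The GEM-X gene expression library held 234563105 UMIs, and the v3.1 library held 178214937 UMIs. The hashtag libraries held 21073911 UMIs (GEM-X) and 13452426 UMIs (v3.1). After filtering, 32331 cells carried exactly 1 hashtag. Mouse 1 gave 3868 tdTomato-positive and 12143 tdTomato-negative cells, and mouse 2 gave 3935 and 12385. Per tube and chemistry, the summed counts ran from 13883381 UMIs (mouse 2, positive, v3.1) to 78795800 UMIs (mouse 1, negative, GEM-X). Median depth per cell ran from 6650 to 10026 UMIs.

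Tppp3 (ENSMUSG00000014846) itself was barely detected in the adult cells. A Tppp3 UMI was found in 0.543% of tdTomato-positive cells of mouse 1 (exact 95% interval 0.34 to 0.83%) and in 0.610% of those of mouse 2 (0.391 to 0.906%). In tdTomato-negative cells the shares were 0.502% (0.385 to 0.645%) and 0.517% (0.398 to 0.659%). Median depths of these tubes were 9094.5, 7731, 9314 and 7855 UMIs. Of the B cell-like cells, a class that should lack the gene, 0 of 194 had a UMI at a median depth of 7103 UMIs, which an exact interval allows up to 1.88%. That class was too small to measure a background share, so the shares in the 4 tubes are not read as expression. The Tppp3 difference between gates (log2 fold change 0.20 ± 0.29, SE of the fit, n = 2 mice) did not pass edgeR's quasi-likelihood test (adjusted p = 0.999). Positive against negative tubes had 0.504 against 0.494 CPM in mouse 1 and 0.718 against 0.565 in mouse 2. The chemistries disagreed within each mouse. The positive tube was lower with GEM-X in mouse 1 (0.242 against 0.470) and with v3.1 in mouse 2 (0.648 against 0.770). Transcripts of tdTomato and Cre were not analysed here.

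The comparison of tdTomato-positive with tdTomato-negative cells asked what sets cells with a history of neonatal Tppp3 activity apart, the stated purpose being a possible mechanism under the Tppp3 program. Over all cells, Pf4, F13a1 and Ms4a3 were among the genes that rose in tdTomato-positive cells, and Gt(ROSA)26Sor and Hbb-bs among those that fell. Pf4 (platelet factor 4, a chemokine of platelet granules; ENSMUSG00000029373; mm10 chromosome 5, 90772435 to 90773383) rose 2.06-fold, a log2 fold change of 1.04 ± 0.04 (SE of the fit, n = 2 mice; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.87e-72). Pf4 was higher in both mice, by 1.30 and 0.76 on the log2 scale, and resampling of cells gave a 95% interval of 0.39 to 1.61. Each SE printed for a fold change is that of the fit, which pools the spread over genes, and can be far smaller than the spread between the 2 mice. F13a1, the coagulation factor XIII A chain (ENSMUSG00000039109; chromosome 13, 36867178 to 37050244), rose by 1.12 ± 0.07 (edgeR adjusted p = 1.15e-36), by 1.46 in mouse 1 and 0.46 in mouse 2 (resampling interval 0.43 to 1.41). F13a1 was among the genes most raised in the granulocyte-monocyte progenitor-like cluster, and not among those most raised in the megakaryocyte-platelet-like cluster. Gt(ROSA)26Sor, the non-coding transcript of the Rosa26 locus (ENSMUSG00000086429; chromosome 6, 113067428 to 113077333), fell to a log2 fold change of -0.50 ± 0.05 (edgeR adjusted p = 2.57e-16), lower in both mice (-0.48 and -0.55). The end of Gt(ROSA)26Sor overlaps the end of Thumpd3 on the opposite strand. Use of strand in counting is not given in the sources used here, so the value of Gt(ROSA)26Sor is uncertain to that extent.

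The other genes named by the fixed rule rose or fell by less than Pf4. Ms4a3 (ENSMUSG00000024681; chromosome 19, 11629496 to 11640851), a marker of granulocyte-monocyte progenitors, rose by 0.86 ± 0.06 (edgeR adjusted p = 3.30e-36), by 1.4 in mouse 1 and 0.03 in mouse 2 (resampling interval 0.37 to 1.06). The granule protease genes Ctsg (0.57) and Prtn3 (0.43) and the myeloperoxidase gene Mpo (0.38) rose with it, each with an SE of 0.04 (n = 2 mice). Anxa3 (0.50), Nrg2 (0.43), Fkbp11 (0.39) and the myeloid lectin receptor gene Clec12a (0.34) rose by edgeR adjusted p values up to 1.19e-07. The genes that fell were Dscam (-0.31), the interleukin 7 receptor gene Il7r (-0.29), Spire1 (-0.28), the haem-pathway genes Blvrb (-0.27) and Hebp1 (-0.27), Camsap2 (-0.25), Slc16a11 (-0.23) and Hnf4a (-0.23), with SEs of 0.04 to 0.07 and edgeR adjusted p values up to 0.0402. The rule requires the same sign in both mice, but in mouse 2 Mpo (0.0086), Prtn3 (0.0088), Ms4a3 and Ctsg (0.085) were near 0.

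Gene lists fixed beforehand were tested with camera at a preset correlation of 0.01, and all lists that passed had adjusted p values of 0.516 or more with an estimated correlation. Between the gates the test with an estimated correlation had 1 residual degree of freedom, and it missed simulated shifts of 0.5. Its p values therefore cannot tell a shifted list from an unshifted one. Of 20 megakaryocyte-platelet genes, 19 were higher and 7 rose, 8 adjusted over the list alone (adjusted p = 3.25e-16; adjusted p = 0.516 with an estimated correlation). Beside Pf4 these included Rab27b (log2 0.21 ± 0.05), Cd9 (0.15 ± 0.04) and the integrin gene Itga2b (0.18 ± 0.05), each higher in both mice. Of 15 granulocyte-monocyte progenitor genes, 14 were higher and 11 rose, 14 adjusted over the list alone (adjusted p = 3.39e-44; adjusted p = 0.516 with an estimated correlation). Ly6c2 (0.84) and the elastase gene Elane (0.73) joined Ms4a3 and Ctsg there, but Elane was 1.5 higher in mouse 1 and -0.17 in mouse 2. Of 16 erythroid genes 0 were higher and 7 fell, 10 adjusted over the list alone (adjusted p = 3.04e-32; adjusted p = 0.516 with an estimated correlation). The haemoglobin genes Hbb-bs (-2.17 ± 0.10) and Hba-a1 (-1.68 ± 0.14), which have near-identical copies, fell in both mice, while Car1 (-0.50) and Ermap (-0.79) were lower in mouse 2 alone. The fall of Hbb-bs rests on few cells. Its UMIs came from 107 and 127 cells in the negative tubes of mouse 1 and mouse 2. There 1 cell held 482 of 1322 UMIs and 187 of 1043. Of 12 lymphoid progenitor genes, Il7r and Ccr9 (-0.41 ± 0.12) fell, 3 passed adjusted over the list alone (adjusted p = 6.06e-04; adjusted p = 0.713 with an estimated correlation), and Ccr9 was -0.72 in mouse 1 and 0.18 in mouse 2. The resampling intervals of Car1 (-1.18 to 0.073), Il7r (-0.59 to 0.037) and Ccr9 (-0.75 to 0.13) included 0.

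Among 19 immediate early and stress genes, Jun (log2 0.31 ± 0.03), Fos (0.63 ± 0.09), Fosb (0.58 ± 0.11) and Egr1 (0.32 ± 0.07) rose, each in both mice (list adjusted p = 1.37e-06; adjusted p = 0.574 with an estimated correlation; 4 adjusted over the list alone). These genes encode transcription factors induced within minutes of a stimulus. Of 18 genes of aged HSCs, the caveola gene Cavin2 (0.57 ± 0.08) and the von Willebrand factor gene Vwf (0.36 ± 0.09) rose in both mice, 5 adjusted over the list alone (adjusted p = 6.63e-04; adjusted p = 0.516 with an estimated correlation). Of 10 fetal and neonatal HSC genes, Hmga2 (-0.18 ± 0.03) fell in both mice, 1 adjusted over the list alone (adjusted p = 0.0424; adjusted p = 0.574 with an estimated correlation). Of 5 mast-basophil genes, Cpa3 (0.29 ± 0.04, both mice) and Ms4a2 (0.78 ± 0.20; -0.01 in mouse 2; resampling interval -0.17 to 1.4) rose, 4 adjusted over the list alone (adjusted p = 1.08e-09; adjusted p = 0.516 with an estimated correlation). Of 23 G2/M phase genes all were higher and Ube2c, Cenpf, Ccnb2 and Ccnb1 rose by 0.12 to 0.16, 19 adjusted over the list alone (adjusted p = 1.47e-21; adjusted p = 0.516 with an estimated correlation).

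Of 14 HSC genes, 3 were higher and 0 passed in either direction by edgeR, 1 adjusted over the list alone (lower; adjusted p = 0.027; adjusted p = 0.656 with an estimated correlation). Of 13 microtubule and TPPP family genes, Tuba1c (log2 0.20), Tuba8 (0.39) and Tuba4a (0.11) rose, 3 adjusted over the list alone (adjusted p = 1.84e-04; adjusted p = 0.516 with an estimated correlation). Of 11 replication-dependent histone genes, Hist1h2ac (0.19) and Hist1h3c (0.11) rose, 5 adjusted over the list alone (adjusted p = 1.15e-09; adjusted p = 0.516 with an estimated correlation). The neutrophil genes S100a8, Ltf and Camp passed as higher, 3 adjusted over the list alone (adjusted p = 6.79e-04; adjusted p = 0.574 with an estimated correlation), with Ltf (-0.44) and Camp (-0.36) lower in mouse 1. Their 95% intervals from resampling cells spanned 0 widely, from -2.58 to 1.71 for S100a8, -3.24 to 2.73 for Ltf and -3.40 to 2.06 for Camp. Of 15 glycolysis genes Pgam1 (0.11) rose, 1 adjusted over the list alone (adjusted p = 3.51e-04; adjusted p = 0.656 with an estimated correlation). No gene passed in the lists of oxidative phosphorylation (adjusted p = 0.00176; adjusted p = 0.749 with an estimated correlation), mitochondrially encoded genes (adjusted p = 0.0057; adjusted p = 0.713 with an estimated correlation) or B cell genes (adjusted p = 0.0017; adjusted p = 0.574 with an estimated correlation), and 0, 0 and 2 passed adjusted over the list alone. The remaining lists did not pass: quiescence regulators (adjusted p = 0.213), T and NK cell (0.419), macrophage-dendritic (0.972), endothelial-stromal (0.972), G1/S phase (0.834), type I interferon response (0.067), MHC class II (0.0786), cytokine and niche receptors (0.419) and ribosomal proteins (0.266). Within these, Gata2 (0.12) rose in both mice, Nkg7 (0.13) rose but was -0.01 in mouse 2, and Clec9a (1.13) rose but was -0.36 in mouse 1. The resampling intervals of Hist1h3c (-0.015 to 0.22) and Clec9a (-0.70 to 1.34) included 0.

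Over all cells 212 of 16585 genes passed edgeR's test, 140 higher and 72 lower in tdTomato-positive cells, and 148 of them had the same sign in both mice and both chemistries. The fit left 1 residual degree of freedom per gene. Without the mouse as a block edgeR called 0 genes (102 at an unadjusted p under 0.05). DESeq2 called 5 (87 at an unadjusted p under 0.05), namely Hbb-bs, Hba-a1, Epx, Cxcl10 and Gt(ROSA)26Sor. GEM-X counts alone gave 5 genes, namely Pf4, Gt(ROSA)26Sor, Jun, Cpa3 and Cavin2. Epx, Cxcl10, Igha and Prg2 are named after their values were seen. Fits without 1 tube had no mouse block: without the positive tube of mouse 1 edgeR called 0 genes (123 unadjusted), F13a1 came to 0.037, Ms4a3 to -0.19, Ctsg to -0.35, Anxa3 to -0.38, Prtn3 to -0.30 and Mpo to -0.29. Such a fit sets the lone tube partly against the other mouse. Within mouse 2 the log2 ratios were 0.46 for F13a1, 0.14 for Anxa3, 0.085 for Ctsg, 0.030 for Ms4a3, 0.0088 for Prtn3 and 0.0086 for Mpo, against 0.68 to 1.46 for these genes in mouse 1. Without the negative tube of mouse 1 the call was Igha alone (Il7r 0.27), without the positive tube of mouse 2 Prg2 alone (Il7r 0.029), and without the negative tube of mouse 2 edgeR called 0 genes (56 unadjusted; Blvrb 0.12). With the granulocyte-monocyte, erythroid, B and T/NK-like clusters left out F13a1 was 0.11, and with the megakaryocyte-platelet-like cluster left out too Pf4 was -0.017. The 0.25% of cells richest in Pf4 held 69% and 68.8% of its UMIs in the positive tubes and 50.6% and 53.1% in the negative tubes. Without these cells Pf4 was 0.63 higher in mouse 1 and 0.18 higher in mouse 2.

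**Figure D1:**
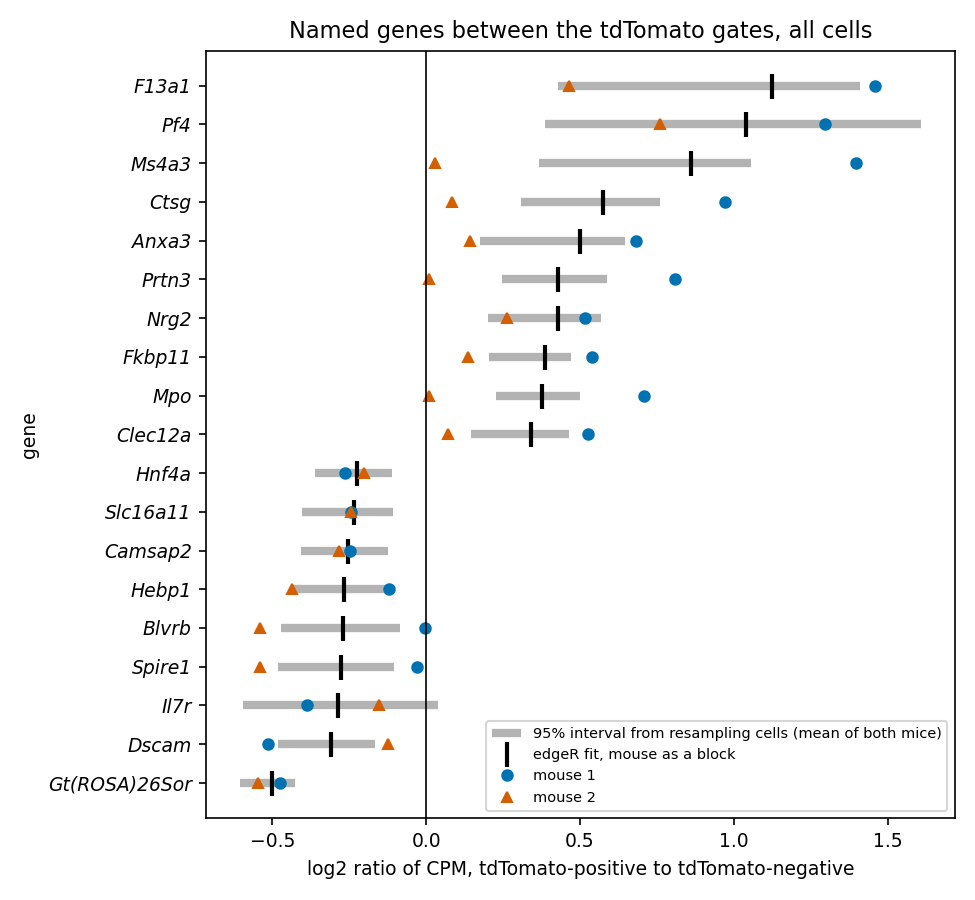
Log2 fold change of tdTomato-positive over tdTomato-negative cells for 19 genes named by the fixed rule over all cells; the tick is the edgeR value, circles are mouse 1, triangles mouse 2, and grey bars the 95% interval from resampling cells. Pf4 (1.30 and 0.76) was above 0 in both mice, Ms4a3 was 1.4 in mouse 1 and 0.03 in mouse 2, and Gt(ROSA)26Sor was below 0 in both.

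The HSC-like cells were compared next, since a difference over all cells can be one of composition and the title concerns platelet-biased HSCs. HSC-like clusters held 9759 cells, and 1 of these clusters was also led by interferon genes (Iigp1, Ifit1, Ifi44). Gt(ROSA)26Sor fell in HSC-like cells as well (log2 fold change -0.52 ± 0.11, SE of the fit, n = 2 mice; edgeR adjusted p = 0.00196; -0.53 and -0.51 per mouse). Jun (ENSMUSG00000052684; chromosome 4, 95049034 to 95052222) rose by 0.26 ± 0.05 (edgeR adjusted p = 1.67e-04), by 0.40 in mouse 1 and 0.11 in mouse 2. Cmss1 (0.09 ± 0.01), Camk1d (0.08 ± 0.02) and the nuclear non-coding RNA gene Malat1 (0.04 ± 0.01) rose by small amounts in both mice (edgeR adjusted p up to 0.0389). Cmss1 and Camk1d also depended strongly on the chemistry, being 10.2-fold and 7.68-fold higher with GEM-X over all cells. Both were called from GEM-X counts alone and not from v3.1 counts alone. Whether their small rises are technical was not tested. Fos, chosen after its values were seen, rose by 0.63 ± 0.14 (0.84 and 0.47 per mouse). Pf4 was 0.09 ± 0.09 higher within HSC-like cells clustered without the genes called between the gates and did not pass.

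In HSC-like cells 12 of 14133 genes passed edgeR's test, 9 higher and 3 lower. Camera passed the immediate early genes, with Jun and Fos risen and 4 adjusted over the list alone (adjusted p = 0.00237), the aged HSC genes, with 0 risen and 2 adjusted over the list alone (0.0075), and the histones, with Hist1h2ac risen and 1 adjusted over the list alone (0.0205), and each of these 3 lists had adjusted p = 0.957 with an estimated correlation. Without the mouse block edgeR called 0 genes (200 at an unadjusted p under 0.05), and DESeq2 called 1, Cxcl10 (14 unadjusted). Without the positive tube of mouse 1 edgeR called 1 gene and Jun was -0.0021 and Cmss1 0.0084. The count was 5 without the negative tube of mouse 1 and 0 without the positive tube of mouse 2 (Malat1 -0.018 in either case), and 4 without the negative tube of mouse 2 (Cmss1 -0.0083).

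In the megakaryocyte-platelet-like cluster, a comparison added after the data were seen, the genes that rose in tdTomato-positive cells included Pf4, Vwf and Ltbp1. Pf4 rose by 0.98 ± 0.04 (SE of the fit, n = 2 mice; edgeR adjusted p = 6.84e-109; 1.43 and 0.52 per mouse). Vwf (ENSMUSG00000001930; chromosome 6, 125546774 to 125686679), a platelet adhesion protein gene, rose by 0.65 ± 0.14 (edgeR adjusted p = 0.00316; 1.11 and 0.23 per mouse). Ltbp1, which binds latent TGF-beta (ENSMUSG00000001870; chromosome 17, 75005568 to 75392512), rose by 1.13 ± 0.25 (edgeR adjusted p = 0.00239; 1.65 and 0.71 per mouse). Jun (0.51 ± 0.09), Serpine2 (0.80 ± 0.20), Cavin2 (0.34) and the division genes Ccnb2 (0.34), Cenpf (0.30), Ckap2l (0.29) and Kif20b (0.29) rose with edgeR adjusted p values up to 0.0402. Dok6 (-0.62 ± 0.13), Chm (-0.58 ± 0.14), the progenitor antigen gene Cd34 (-0.29 ± 0.07), Pim1 (-0.28) and Lcp1 (-0.26) fell with edgeR adjusted p values up to 0.0221. All 15 moved the same way in both mice, but the 95% intervals from resampling cells included 0 for Cenpf (-0.0054 to 0.59), Serpine2 (-0.34 to 1.59) and Cavin2 (-0.033 to 0.66).

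In this cluster 33 of 11607 genes passed edgeR's test, 27 higher and 6 lower. Of 20 platelet-lineage genes, 16 were higher and 3 rose, 7 adjusted over the list alone (camera adjusted p = 2.68e-18; adjusted p = 0.581 with an estimated correlation). Of 23 G2/M phase genes, 21 were higher and 4 rose, Mki67 (0.23 ± 0.04; resampling interval -0.024 to 0.45) among them, 11 adjusted over the list alone (adjusted p = 1.01e-17; adjusted p = 0.581 with an estimated correlation). Of 11 histone genes all were higher and 5 rose, Hist1h3c (0.36 ± 0.05) among them, 10 adjusted over the list alone (adjusted p = 2.33e-20; adjusted p = 0.581 with an estimated correlation). Smaller list shifts were upward for aged HSC (3.02e-04), erythroid (0.00639), immediate early (0.00639) and mast-basophil genes (0.00715) and downward for interferon genes (8.82e-04), with 2, 1, 1, 2 and 2 genes adjusted over the list alone, and these 5 lists too had adjusted p = 0.581 with an estimated correlation. Without the mouse block edgeR called 0 genes (361 at an unadjusted p under 0.05), and DESeq2 called 0 (27 unadjusted). In the clusters led by Pf4 once the genes called between the gates were left out of the clustering, 6 genes passed, namely Pf4 (0.92 ± 0.04), Jun, Dok6, Mrvi1, Tmsb4x and Rap1b, while Vwf (0.54), Ltbp1 (0.96) and the division genes Cenpf (0.19), Ccnb2 (0.17), Ckap2l (0.14) and Kif20b (0.11) did not. Mrvi1, Tmsb4x and Rap1b are named after their values were seen.

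**Figure D2:**
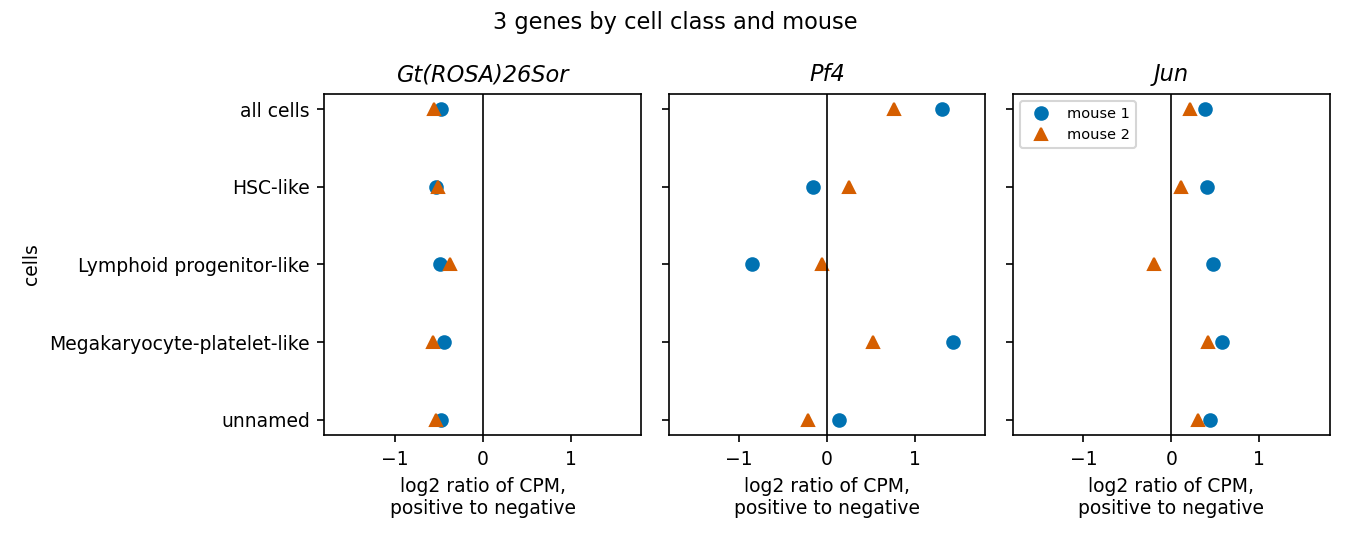
Log2 ratio of tdTomato-positive to tdTomato-negative CPM for Gt(ROSA)26Sor, Pf4 and Jun in each cell class, circles for mouse 1 and triangles for mouse 2. Gt(ROSA)26Sor lay between -0.57 and -0.37 in HSC-like, lymphoid progenitor-like and megakaryocyte-platelet-like cells of both mice, while Pf4 was 1.43 and 0.52 in megakaryocyte-platelet-like cells and -0.16 and 0.25 in HSC-like cells.

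In the lymphoid progenitor-like clusters, also added after the data were seen, 5 of 12713 genes passed edgeR's test. Auts2 (ENSMUSG00000029673; chromosome 5, 131437333 to 132543344) fell (log2 fold change -0.31 ± 0.05, SE of the fit, n = 2 mice; edgeR adjusted p = 2.55e-06; -0.34 and -0.27 per mouse), and so did the kinase gene Prkg1 (-0.65 ± 0.11; edgeR adjusted p = 1.10e-05; -0.87 and -0.20). Outside the naming rule and named after their values were seen, Hist1h2ac (0.57 ± 0.10) rose in both mice, the chemokine gene Ccl5 (-1.47 ± 0.25) fell in both, and Jun (0.31 ± 0.07) rose but was -0.20 in mouse 2 (resampling interval -0.083 to 0.37). Without the mouse block edgeR called 0 genes (114 at an unadjusted p under 0.05) and DESeq2 called 0 (10 unadjusted). The histone (camera adjusted p = 5.39e-05; 5 adjusted over the list alone), immediate early (0.0109; 1 adjusted over the list alone), ribosomal (9.16e-04), interferon (0.0175) and oxidative phosphorylation lists (0.0413) and the erythroid list, downward (0.00384), passed, the last 4 with 0 genes adjusted over the list alone, each with adjusted p = 0.713 with an estimated correlation.

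HSC-like cells made up a slightly smaller share of tdTomato-positive than of tdTomato-negative tubes. In mouse 1 the share was 24.2% (exact 95% interval 22.9 to 25.6%) against 25.7% (24.9 to 26.4%), and in mouse 2 it was 33.6% (32.1 to 35.1%) against 35.4% (34.6 to 36.3%), with overlapping intervals in both mice. Clustered without the genes called between the gates, clusters led by Pf4 held 4.91% (4.25 to 5.64%) of positive against 3.95% (3.61 to 4.31%) of negative cells in mouse 1, and 7.62% (6.81 to 8.50%) against 5.40% (5.01 to 5.81%) in mouse 2. In the same clustering the cluster led by Elane went from 1.53% of negative to 3.49% of positive cells in mouse 1 and from 0.896% to 0.915% in mouse 2. The cluster led by Car1, an erythroid gene, went from 0.329% to 0.362% in mouse 1 and from 0.743% to 0.381% in mouse 2, and the lymphoid cluster led by Dntt from 8.49% to 7.96% and from 2.25% to 2.01%. At resolution 0.5, with those genes in the clustering, the megakaryocyte-platelet-like share in the positive tube minus the negative was -0.512 percentage points in mouse 1 and 1.83 in mouse 2. In the clustering with all genes at resolution 1, clusters left unnamed held 47.2% of negative and 47.3% of positive cells in mouse 1, and 46.2% and 47.5% in mouse 2. With 2 pairs the smallest two-sided exact permutation p is 0.5, so no share is called changed.

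**Figure D3:**
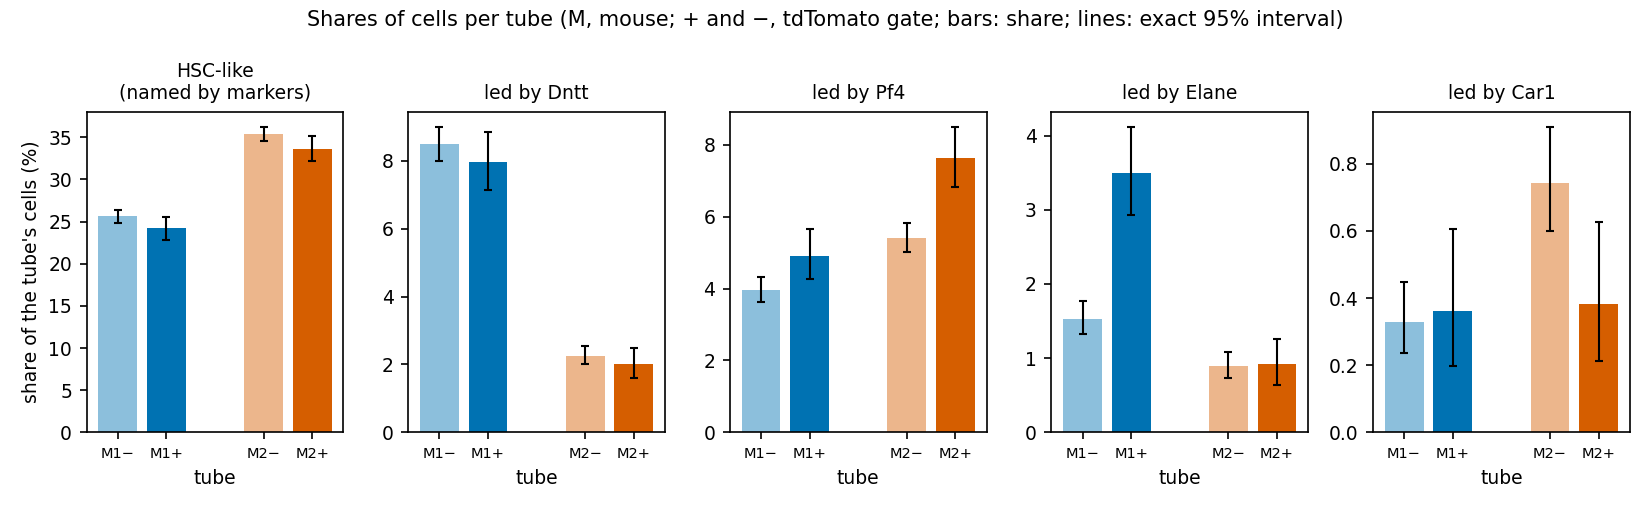
Share of cells (%) per tube with exact 95% intervals. HSC-like clusters are those of the clustering with all genes. The clusters led by Dntt, Pf4, Elane and Car1 are those of the clustering without the genes called between the gates. In the latter clustering the Pf4-led share was higher in the positive tube of both mice (4.91% against 3.95% and 7.62% against 5.40%), and the Elane-led share in mouse 1 (3.49% against 1.53%).

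GEM-X was compared with v3.1 because the study set out to compare both technologies on cells of the same tubes. Which matrix belongs to which chemistry was inferred from its name and Cell Ranger version, and every direction between GEM-X and v3.1 rests on that. The median cell held 9241 ± 804 UMIs (SD, n = 4 tubes) with GEM-X and 7471 ± 818 with v3.1, a ratio of 1.24 that ranged from 1.21 to 1.29 between tubes. Reads per cell were not examined, and each chemistry had 1 gene expression library. How deeply each library was sequenced therefore cannot be told apart from the chemistry in these ratios. Median genes per cell were 3665 ± 168 and 3121 ± 211, a ratio of 1.18, which fell to 1.04 once every cell was thinned to 5000 UMIs. Thinning left out 6.36% of GEM-X and 16% of v3.1 cells, which had fewer UMIs. Mitochondrial UMIs were 1.93% with GEM-X and 2.60% with v3.1. Each of these differences had the same direction in 4 of 4 tubes, and the two-sided exact permutation p of 0.13 is the smallest that 4 pairs allow, so none is called. Of the cells kept, 10.4% with GEM-X and 14.1% with v3.1 carried more than 1 hashtag.

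The genes named by the fixed rule between the chemistries included mitochondrial transcripts on both sides. The ATP synthase gene mt-Atp8 (ENSMUSG00000064356; mitochondrial genome, 7766 to 7969) was 44.6-fold higher with GEM-X (log2 5.48 ± 0.03, SE of the fit, n = 4 tubes; edgeR adjusted p = 2.50e-26). The interleukin 31 receptor gene Il31ra (4.91 ± 0.07) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (4.35 ± 0.02; ENSMUSG00000035202; chromosome 9, 123366927 to 123462666) came next, followed by mt-Nd4l (3.66), Cmss1 (3.35), Camk1d (2.94), mt-Nd5 (2.45), Tgtp2 (2.39), Coro1b (2.36) and Ahnak (1.98). Lower with GEM-X were Lrrc4 (-2.61 ± 0.04; ENSMUSG00000049939; chromosome 6, 28661831 to 28831747), Insyn2b (-2.50 ± 0.07), Cdk2ap1 (-1.8), Snhg9 (-1.8), Hypk (-1.29), Nr6a1 (-1.24), Ctxn1 (-1.20), Acot2 (-1.19) and Tmsb15b2 (-1.09). Cytochrome b, mt-Cytb, was lower as well (-1.42 ± 0.02; edgeR adjusted p = 2.17e-20), opposite to mt-Nd5 of the same strand. All 20 had the same direction in 4 of 4 tubes and edgeR adjusted p values up to 2.06e-13. The transcripts of mt-Atp8 and mt-Nd4l overlap those of mt-Atp6 and mt-Nd4, and Tgtp2 and Tmsb15b2 have near-identical copies, so reads of these are shared and their values uncertain.

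Of 11 replication-dependent histone genes, 10 were higher and 1 lower with GEM-X, 11 adjusted over the list alone (camera adjusted p = 2.08e-05; adjusted p = 0.726 with an estimated correlation), with Hist1h4d (log2 4.19 ± 0.02) and Hist1h3c (4.21) in the lead. Ribosomal protein genes were mostly lower (23 of 29, 29 adjusted over the list alone; adjusted p = 3.21e-06; adjusted p = 0.726 with an estimated correlation), with Rps2 (-0.88) lower and Rpl4 (0.76) higher. Nuclear-encoded oxidative phosphorylation genes were mostly lower (18 of 24, 23 adjusted over the list alone; adjusted p = 7.02e-05; adjusted p = 0.726 with an estimated correlation), and Ndufb9 (-0.76) and Cox5a (-0.69) were among them. G2/M phase genes were mostly higher (16 of 23, 21 adjusted over the list alone; adjusted p = 0.0111; adjusted p = 0.726 with an estimated correlation), with Mki67 at 1.70 and Top2a at 0.92. Immediate early (14 of 19 lower; 0.026; Jund -1.08), MHC class II (6 of 7 lower; 0.0301; Cd74 -0.70) and microtubule genes (9 of 13 lower; 0.0301; Stmn1 -0.55) passed too, with 17, 6 and 11 genes adjusted over the list alone. These 3 lists too had adjusted p = 0.726 with an estimated correlation. The mitochondrially encoded list did not pass (adjusted p = 0.369), its mean (0.65) being above 0 and its median (-0.11) and test pointing down.

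In all, 11608 of 15862 genes passed edgeR's test between the chemistries, 5872 higher and 5736 lower with GEM-X, and 1362 differed by more than 1 on the log2 scale. The 4 tubes shared 1 library per chemistry, so the spread is that between tubes and not between libraries, and the Cell Ranger version differed along with the chemistry.

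**Figure D4:**
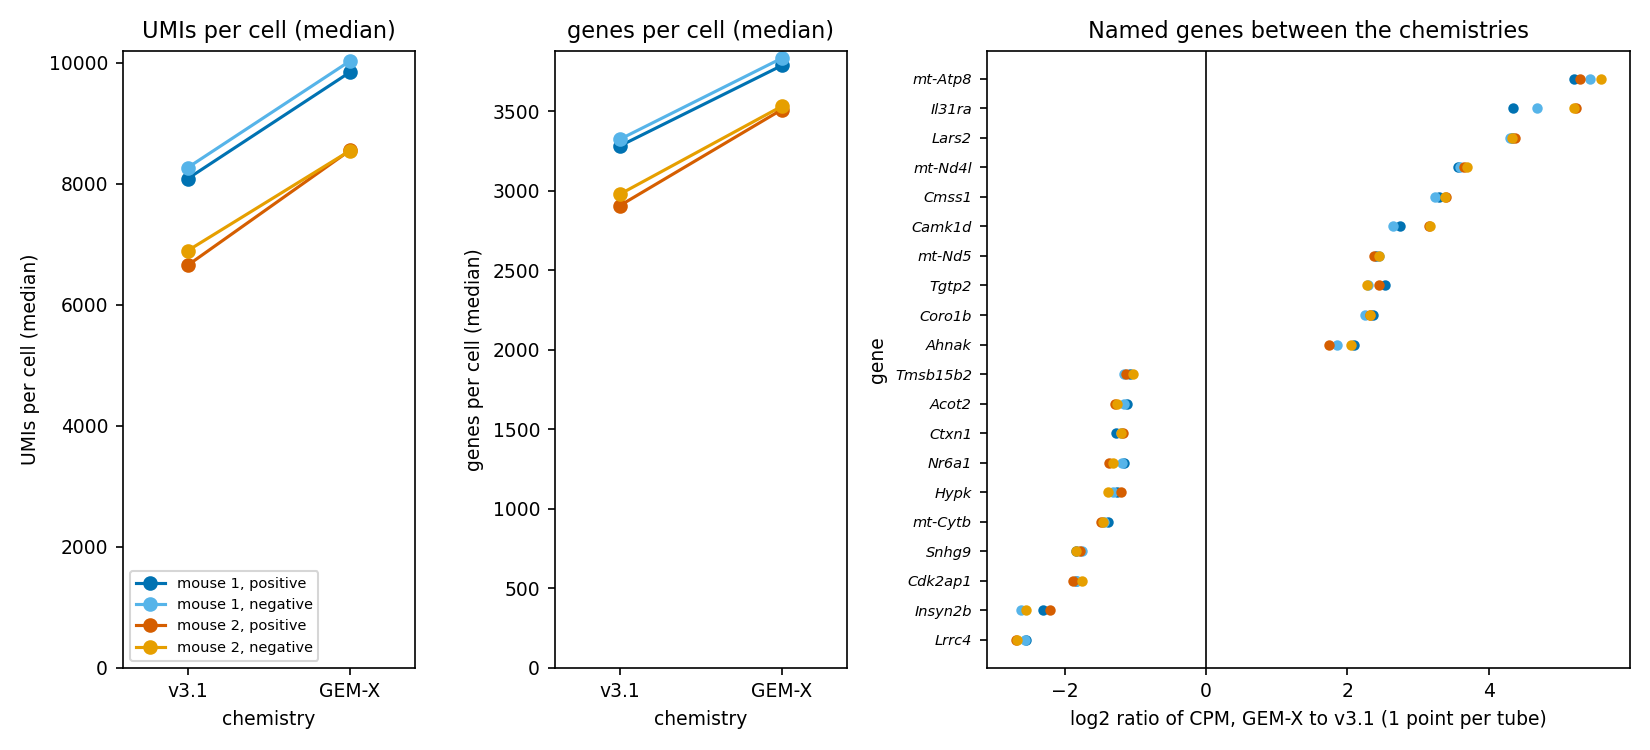
Median UMIs and median genes per cell of each tube by chemistry, and the log2 ratio of GEM-X to v3.1 for the 20 genes named by the fixed rule, 1 point per tube. UMIs per cell were higher with GEM-X in 4 of 4 tubes (ratio 1.21 to 1.29), mt-Atp8 was highest at 5.48 and Lrrc4 lowest at -2.61.

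The effect of the tdTomato gate was then compared between the chemistries. It differed for 7 of 15862 genes by edgeR's interaction test: Ccl5, Prg2, Igkc, Tcrg-C1, Cxcl10, Prg3 and Trbc2. None of the genes named by the rule over all cells was among them. Ccl5 (ENSMUSG00000035042; chromosome 11, 83525778 to 83530518) differed by 1.28 ± 0.13 (SE of the fit, n = 4 tubes; edgeR adjusted p = 2.10e-04). For Prg2 and Igkc a single cell held 93.4% and 88.7% of the UMIs. A single cell held 42.4% and 51.4% of the Ccl5 UMIs in the GEM-X positive tubes, and 31.0% and 44.1% in those of v3.1. DESeq2 called 2 genes, Ccl5 and Tcrg-C1. Camera passed the granulocyte-monocyte (downward, adjusted p = 8.73e-06), T and NK cell (upward, 8.73e-06), megakaryocyte-platelet (downward, 0.0396), G2/M phase (upward, 0.0103) and histone lists (upward, 0.0103), with 2, 1, 0, 0 and 3 genes adjusted over the list alone and each with adjusted p = 0.706 with an estimated correlation.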

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

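The interaction test was planned, and the comparison with other splits of the samples was chosen after its result was seen.

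The effect of the tdTomato gate differed between GEM-X and v3.1, by a test of the difference itself, for 7 genes. On the log2 scale the gate effect with GEM-X minus that with v3.1 was 1.28 for Ccl5, 7.81 for Prg2, 4.48 for Igkc, 5.49 for Tcrg-C1, -4.87 for Cxcl10, 4.60 for Prg3 and 1.86 for Trbc2. The richest cell held 5.29% of the UMIs of Ccl5, 93.4% of Prg2, 88.7% of Igkc, 20.9% of Tcrg-C1, 18.7% of Cxcl10, 49.1% of Prg3 and 2.35% of Trbc2. Within the GEM-X positive tubes of mouse 1 and mouse 2 a single cell held 42.4% and 51.4% of the Ccl5 UMIs and 88.2% and 79.3% of the Tcrg-C1 UMIs. Within the v3.1 positive tubes a single cell held 31.0% and 44.1% of the Ccl5 UMIs. Tcrg-C1 had 0 UMIs there in mouse 1, and a single cell held 80% of 5 UMIs in mouse 2. In the v3.1 positive tube of mouse 1 a single cell held 64.5% of the Cxcl10 UMIs. In the other tubes and chemistries this share ran from 10.5% (mouse 2, negative, GEM-X) to 73.5% (mouse 2, negative, v3.1). No explanation was weighed for these 7 genes.

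The 28 groups of 4 values tested for a sample far from the others gave 0 such samples by Dixon's test. Chance flags about 1 in 20 groups.

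The real split of the 8 sums into GEM-X and v3.1 gave 11608 genes. Of the 8 splits that part all 4 tubes, 1 gave as many, the real one, and the highest of the other 7 gave 0. These splits are too few for a share under 0.05. The other 7 splits mix the chemistries on both sides. Splits that keep whole tubes together were fitted without the tube as a block, and mouse 1 against mouse 2 gave 301 genes and the gates 0.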

How the results depend on the processing

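The comparisons within megakaryocyte-platelet-like and lymphoid progenitor-like cells, the removal of clusters from the comparison of all cells or of HSC-like cells, the unfloored dispersions, the clusters led by Pf4 and DESeq2 for the gate by chemistry were chosen after the data were seen. All other alternatives were fixed before the data were examined.

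The number of genes called between the gates over all cells (212 in the reported fit) was 0 without the mouse as a block, 5 with DESeq2, 140 with DESeq2 size factors, 5 from GEM-X alone, 61 from v3.1 alone, 144 with the largest hashtag, 24 after Scrublet, 36 with the strict cell filter, 55 without the granulocyte-monocyte, erythroid, B, T/NK-like and megakaryocyte-platelet-like clusters and 27 without the low-UMI cluster. Only 34 of these 55 were among the 212. With the megakaryocyte-platelet-like cluster kept, 143 genes were called, 70 of them among the 212. Of the calls under the other alternatives in this list most were among the 212, such as 54 of 61 from v3.1 and 138 of 144 with the largest hashtag. Leaving out 1 tube, fitted without the block so that the lone tube of a gate is assumed to vary like the others, gave 0 to 1 genes. The prior degrees of freedom that edgeR estimated were 308 in the reported fit, 57 with DESeq2 size factors, 12.1 after Scrublet and 2.64 without the block. In HSC-like cells (12) the count was 0 without the block, 1 with DESeq2, 4 from GEM-X, 5 from v3.1, 7 with the largest hashtag, 7 at resolution 2, 7 clustered without the called genes, 6 without the interferon-led cluster and 0 to 5 without 1 tube. In megakaryocyte-platelet-like cells (33) it was 0 without the block, 0 with DESeq2, 14 from v3.1 and 6 in the clusters led by Pf4. Among the 33 were 5 of these 14, all 6 from the clusters led by Pf4, and 23 of 49 genes called from GEM-X. In lymphoid progenitor-like cells (5) the count was 0 without the block, 0 with DESeq2, 12 from GEM-X and 1 from v3.1. The 12 included all 5 reported genes, and the 1 from v3.1, Kcnq5, was not among them. The gate by chemistry gave 2 genes with DESeq2 (7 with edgeR). The cause was not tested for these counts. Between GEM-X and v3.1 no alternative moved the count of 11608 by over 1.5 times (9444 to 11837).

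Of 340 values of the 20 genes that the naming rule picks over all cells, 323 kept their direction, 115 of these with the call, and 17 reversed. Without the granulocyte-monocyte, erythroid, B and T/NK-like clusters Blvrb was 0.035 and Hebp1 0.0085, and without the megakaryocyte-platelet-like cluster as well Pf4 was -0.017 and Hebp1 0.012. Leaving out 1 tube gave Ms4a3 -0.19 to 1.61, Ctsg -0.35 to 1.32, Anxa3 -0.38 to 1.09, Prtn3 -0.30 to 1.08, Nrg2 -0.15 to 0.86, Fkbp11 -0.12 to 0.78, Mpo -0.29 to 0.97, Clec12a -0.13 to 0.72, Il7r -0.72 to 0.27, Blvrb -0.64 to 0.12 and Slc16a11 -0.55 to 0.064. In HSC-like cells it gave Jun -0.0021 to 0.52, Cmss1 -0.0083 to 0.19 and Malat1 -0.018 to 0.092. The 200 values of the 20 chemistry genes, the 105 of the megakaryocyte-platelet-like genes, the 12 of the lymphoid genes and the 21 of the gate by chemistry kept their direction.

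The mean difference in share, positive minus negative, was -1.13 percentage points for lymphoid cells at resolution 0.5 (0.661 for megakaryocyte-platelet-like cells there, lower in the positive tube of mouse 1), -1.88 for HSC-like and 0.221 for megakaryocyte-platelet-like cells at resolution 2, 0.395 for erythroid (a name that here takes in a cluster of 612 cells led by Pf4), -2.19 for HSC-like and -0.386 for lymphoid cells clustered without the called genes, -1.97 for HSC-like cells from GEM-X, -1.18 for HSC-like and -0.129 for T and NK cells from v3.1, 0.207 for B cells after Scrublet, and -0.0632 for B cells, -1.07 for HSC-like and -1.12 for lymphoid cells with the strict filter. For T and NK cells the mean difference in share was 0.0947 from GEM-X and -0.00504 with both chemistries. The UMI ratio of GEM-X to v3.1 was 1.27 without a cell filter and the gene ratio 1.04 after thinning. With an estimated correlation 0 lists passed in each of the 6 comparisons. Fry passed 0 lists between the gates in each class, 18 between the chemistries and 0 for the gate by chemistry. The fits left 1 residual degree of freedom per gene between the gates, 3 between the chemistries and 2 for the gate by chemistry. These counts of 0 therefore do not show that no list shifted. Without the block camera passed 10 lists over all cells and 1 in HSC-like cells, and 11 over all cells without those 5 kinds of cluster. Leaving out 1 tube was not run for the megakaryocyte-platelet-like and lymphoid progenitor-like cells or for the gate by chemistry. Of simulated changes of 0.5 on the log2 scale 75.8% were called over all cells and 49.3% for the gate by chemistry, and these simulations did not vary depth, so how far depth limits the calls was not tested.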

Other observations

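The tests of Pf4, Gt(ROSA)26Sor and the immediate early genes and the resampling of cells were chosen only after the results were seen.

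The 2 mice differed in the make-up of the sort. HSC-like cells were 25.7% of the negative cells of mouse 1 and 35.4% of those of mouse 2. Clustered without the genes called between the gates, the cluster led by Dntt, a gene of early lymphoid progenitors, held 8.49% and 2.25%. In the same clustering the cluster led by Ebf1, a B cell gene, held 0.346% and 0.775% of the negative cells.

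Pf4 was 1.04 higher on the log2 scale in tdTomato-positive cells, in both mice. Free RNA or mixing into other cells is argued against as the whole source, since Pf4 within HSC-like cells clustered without the called genes was 0.089 (SE 0.09). Within the clusters led by Pf4 it was still 0.92 higher (SE of the fit 0.04). Resampling cells of the megakaryocyte-platelet-like cluster gave 0.18 to 1.64. A larger number of Pf4-led cells with an unchanged mean Pf4 level is therefore argued against as the whole source. The value of 0.92 rests partly on a few rich cells. It cannot tell a higher level per cell from more Pf4-rich cells within these clusters. Cells with at least 20 Pf4 UMIs were 0.465% and 0.280% of the positive tubes, against 0.206% and 0.226% of the negative tubes. The exact intervals of these shares overlapped in both mice, in mouse 1 only narrowly (0.276 to 0.734% against 0.133 to 0.304%). Such overlap is not a test of the difference. That a few cells carry the rise cannot be told apart from a rise across cells: without the richest 0.25% of cells per tube Pf4 was 0.63 and 0.18 higher, and without the 10 richest cells per tube, the form run first and replaced because tubes differ in cell number, 0.20 and -0.31. A biological difference of cells with a neonatal Tppp3 history may underlie the rise and stays open, as untested.

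Gt(ROSA)26Sor was -0.50 on the log2 scale in tdTomato-positive cells. A different mix of classes is argued against, since within HSC-like cells it was -0.52 (SE 0.11), and so are reads of the overlapping gene Thumpd3, since Thumpd3 was -0.017 (SE 0.04). A candidate explanation is a change at the locus itself, such as recombination of a reporter placed there: all 6 values of HSC-like, lymphoid progenitor-like and megakaryocyte-platelet-like cells in 2 mice lay at -0.37 or lower, and of 22 neighbours within 500000 bp 0 were called by edgeR, with a median of -0.01 and values from -0.44 to 0.43. These extremes were Prrt3 (0.11 CPM) and Cpne9 (0.33 CPM), which were barely detected. Setd5, which starts just past the annotated stretch of Gt(ROSA)26Sor, was -0.11 (SE 0.03) and narrowly missed the call (edgeR adjusted p = 0.0521). On few UMIs (3 to 17 per tube) Gt(ROSA)26Sor was higher in B cell-like cells of mouse 2 (0.48) and in T and NK cell-like cells (1.41 and 0.63), and within the HSC-like cluster led by interferon genes it was -0.087 and -0.14. The labels do not give the reporter's locus, so this stays a hypothesis.

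Jun, Fos, Fosb and Egr1 rose together in tdTomato-positive cells. A different mix of classes is argued against as the whole source, since their mean log2 fold change within HSC-like cells was 0.37. The SE of 0.06 comes from fits of single genes, which are not independent replicates, and leaves out the spread between mice. In HSC-like cells Jun was 0.40 and 0.11 higher per mouse, and Fos was higher in both mice. In the HSC-like cluster led by Il1rapl2, Dlg2 and Ncam2 Jun was 0.42 and -0.21 per mouse. In the other HSC-like clusters Jun was 0.19 to 0.57 higher. Stress from handling of the positive tubes could raise them and cannot be told apart here: the 15 other members of the list had a median of 0.031, with values from -0.11 to 0.46, and the gates were sorted into separate tubes in both mice. A biological difference of the labelled cells stays open, as untested.

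In mouse 1's positive tube 1432 of 1443 Prg2 UMIs came from 1 cell. In mouse 2's negative tube 6552 of 7026 Igkc UMIs came from 1 cell, as did 1418 of 1425 Igha UMIs and 1017 of 1060 Jchain UMIs. Of the 212 genes called over all cells, 28 had at least 50% of their UMIs in 10 cells.

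Over 2000 resamplings of cells within tubes, which cover the sampling of cells and not of mice, the 95% interval left out 0 for 171 of the 212 genes and for 19 of the 20 that the naming rule picks, Il7r being the exception (-0.59 to 0.04). It left out 0 for 8 of 12 called genes in HSC-like cells, for 18 of 33 in megakaryocyte-platelet-like cells (12 of the 15 named, all but Cenpf, Serpine2 and Cavin2) and for 4 of 5 in lymphoid progenitor-like cells. Over all cells the interval was 0.39 to 1.61 for Pf4 and -0.60 to -0.43 for Gt(ROSA)26Sor.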
